A study of Arabidopsis thaliana with 18 samples.

How the data were processed

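The data were 9 peak lists from chromatin immunoprecipitation and sequencing, 6 for H3K9ac (2 libraries for each of WT, hda9-1 and pwr-2) and 3 for H3K14ac (1 per genotype), out of 18 samples. The other 9 samples were inputs and were not analysed here. Seedlings were 10 days old and grown at 23 °C with 16 h of light and 8 h of dark, per the labels' protocols. Chromatin was sheared to about 200 bp and fragments of 300 to 400 bp were selected for the libraries, per the labels' protocols. Sample titles write "hdac" for the libraries whose genotype label is hda9-1, and these were taken as hda9-1.

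Reads were mapped to TAIR10 with Bowtie and enriched islands were called with SICER, per the submitters' processing notes, and the versions of these tools are not given in the sources used here. Each deposited list gives a position and a whole number per peak, and peaks were called separately in each library. That number was read as the count of reads in the peak. The deposited lists have no header, so this meaning was inferred from the values: the count rose with peak width (Spearman correlation 0.797 to 0.938 over the 9 libraries), and in the 1102 peaks with identical position in both WT H3K9ac libraries the counts deviated 1.35 times as much as Poisson counts. The same ratio was 1.03 over 3475 identical peaks of hda9-1 and 1.88 over 1728 of pwr-2. Peak positions moved in steps of 200 bp and the narrowest peak was 200 bp. Whether the authors removed duplicate reads or how they set the threshold of the peak caller is not given in the sources used here.

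Genes came from the RefSeq annotation of TAIR10.1, of which 37887 genes on the 5 nuclear chromosomes were used, 27432 of them protein-coding and 10859 with a symbol. The build of the peaks and that of the annotation have different names, so only peak positions are printed, counted from 1 on TAIR10. Placement was checked by shifting the peaks: in 45 of 45 combinations of library and chromosome, the share of gene bases in peaks was highest with no shift.

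The annotation used gives no strand, so the planned rule on the 500 bp after the transcription start was replaced. A gene counted as marked in a library where its peaks covered at least 50% of the 500 bp at either end of the gene, or of the whole gene where it was shorter. The planned rule for covered length took in 500 bp upstream and was restricted to the gene, and a planned profile around the transcription start was left out. A gene was gained where it was marked in both mutant libraries and neither WT library, and lost in the reverse case. For H3K14ac the rule used the 1 library of each genotype.

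The plan assumed peak lists without counts. Since counts were present, the peaks of the 6 H3K9ac libraries were merged into 12753 regions, and counts of the 8332 regions with a peak in all 6 were tested with edgeR's quasi-likelihood test (TMM factors, no block, all 6 libraries in 1 fit) with Benjamini-Hochberg adjustment at 0.05. The biological coefficient of variation was 0.184. DESeq2 was run as an alternative. In simulated data with 200 changed regions, the edgeR test of hda9-1 against WT called 8%, 26% and 100% of regions raised 1.5-fold, 2-fold and 4-fold, 26% of regions lowered 0.5-fold, and 5 of 8132 unchanged regions. The test was repeated per covered bp, with each library's covered length as an offset and libraries scaled by median read density; in simulated data it called 25% of regions raised 2-fold and 2 unchanged regions. Wider peaks take in weaker flanks, so the test per covered bp can lean low where the test on reads leans high. For genes changed in both marks, the yield-only simulation kept each gene's number of marked libraries of each mark and drew the marks apart.

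Totals were compared with exact permutation tests, two-sided. Overlaps and gene lists were compared with Fisher's exact test, two-sided, over genes that could have been called, with Benjamini-Hochberg adjustment over 12 lists of 252 genes (all matched) and over 20 gene families, of which the immune receptors matched no gene, per mutant. The lists covered flowering time, MIR172 and floral meristem, seed maturation, leaf senescence, warm temperature, abscisic acid and cold, immunity, photosynthesis, housekeeping, the acetylation machinery, pollen and the circadian clock. For the lists, edgeR p-values of regions that overlap a member were also adjusted within each list. Intervals of shares are 95% Wilson intervals and cover counting error only.

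To set gains beside the unequal yield of the libraries, a model with 1 call rate per library was fitted to the genes marked in some but not all H3K9ac libraries, each gene keeping its number of marked libraries, and 1000 sets were drawn from it. Tested on simulated data with 0, 200 and 600 planted gains, it left an excess of 4.08, 67.2 and 333, so where the model holds it absorbs part of a true gain. These data were drawn from the model itself, so the check does not cover a misfit of the model. Where libraries differ in more than 1 call rate each, the excess may also overstate. Call rates were also compared at equal read density in bins of 10 reads per kb. These densities were not raw, as those of the deeper mutant libraries were brought to the level of WT. For gene groups, gains were also compared with protein-coding genes at the same distance from a WT peak, by an exact conditional test over 6 classes of distance. The change in covered length was regressed out of the change in reads as a further check. Chance covariance between the mutants came from counts simulated for all 6 libraries, WT included, with no change between genotypes. Both simulated mutants were set against the same simulated WT libraries. The libraries were drawn independently, so other structure of the real WT libraries is not in the simulation.

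The groups, the tests, the lists, the families, the alternatives and the rule for named genes were chosen before the data were examined, except where stated. The rule named HDA9 and PWR, 11 genes from the literature, the 10 gained and 5 lost genes with a symbol and the largest change in covered length per mutant, the 10 largest among genes marked in all 6 mutant and no WT libraries, and list members that changed, up to 4 per list. Genes outside it, namely those of the read test, the H3K14ac lists, HSP18.2, the genes marked only in WT and those with EMB and SAUR symbols, were chosen after their values were seen. Alternatives were other coverage rules for a marked gene, fewer peaks, protein-coding genes only, other backgrounds, each library left out, and, for the read test, other scaling, filters and a block.

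Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, were used.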

Results

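Acetylation of histone H3 at lysine 9 (H3K9ac) and lysine 14 (H3K14ac) was mapped by chromatin immunoprecipitation and sequencing in 10-day-old Arabidopsis seedlings of the Columbia wild type (WT) and 2 mutants. The hda9-1 mutant lacks the histone deacetylase HDA9, and pwr-2 carries a lesion in POWERDRESS (PWR), a SANT-domain protein. H3K9ac was measured in 2 libraries per genotype and H3K14ac in 1 library per genotype, so no value for H3K14ac has a replicate check. The labels call the H3K9ac replicates biological and do not say whether separate plantings were grown. The p-values of the permutation and edgeR tests therefore measure only the spread between these samples. Those of Fisher's exact test and of the exact stratified test take genes as units and measure no spread between libraries. Neighbouring genes can share a peak, so genes are not independent units. The 9 input samples were not analysed here.

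H3K9ac peaks covered 23.1 and 23.7 Mb of the genome in the WT libraries, 28.7 and 30.5 Mb in hda9-1, and 25.6 and 26.9 Mb in pwr-2. Their number ranged from 11653 in WT replicate 1 to 12890 in pwr-2 replicate 2, with a median width of 1400 bp in every library except hda9-1 replicate 2 at 1600 bp. Between 69.6% and 84.9% of the bases in H3K9ac peaks lay in annotated genes. H3K14ac peaks were narrower, with median widths of 1000 to 1200 bp. They covered 14.9 Mb in WT, 15.7 Mb in hda9-1 and 17.37 Mb in pwr-2, and 93.4% to 93.8% of those bases lay in genes.

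The number of reads inside H3K9ac peaks differed between genotypes with no overlap between WT and either mutant. WT replicates 1 and 2 held 1.95 and 2.22 M reads (M for mega), pwr-2 3.76 and 8.87 M, and hda9-1 12.3 and 18.17 M. For H3K14ac the libraries held 0.668 M in WT, 0.875 M in hda9-1 and 1.09 M in pwr-2. A deeper library lets weaker peaks be called, so every gain in a mutant below stands beside this difference, and a missing WT peak means that none was detected at that depth.

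**Figure D1:**
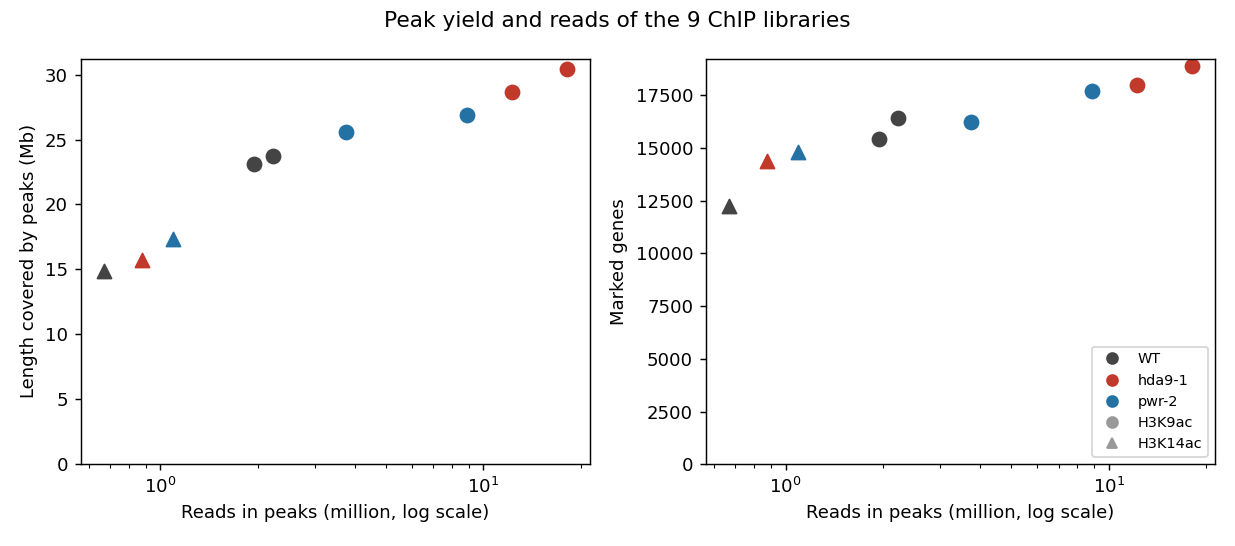
Length covered by peaks (Mb) and number of genes with a marked end, against M reads in peaks on a log axis, for each of the 9 libraries; each point is 1 library. The hda9-1 H3K9ac libraries, at 12.3 and 18.17 M reads, had the most marked genes (17999 and 18901), and the WT libraries lay at or below 2.22 M reads.

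The mutated genes themselves carried H3K9ac peaks in all 6 libraries. Peaks covered 704.5 ± 148 bp of HDA9 (AT3G44680) in WT, 804.5 ± 6.36 bp in hda9-1 and 800 ± 0 bp in pwr-2 (mean ± SD, n = 2 for this and each H3K9ac value below). PWR (AT3G52250) was covered over 963 ± 141 bp in WT, 1263 ± 0 bp in hda9-1 and 1163 ± 141 bp in pwr-2. A peak over the gene does not test for an insertion, so these values do not check the genotype labels.

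The first question was whether loss of HDA9 raised H3K9ac, and at which genes. In hda9-1, 18450 ± 638 genes had a marked end, against 15917 ± 721 in WT. A total of 1449 genes gained the mark, being marked in both hda9-1 libraries and in neither WT library, and 166 genes lost it. Of the gained genes, 1154 were protein-coding and 174 were long non-coding RNAs. Among gained genes with a symbol, the widest gain was at KNAT6, a homeobox gene of the shoot meristem. Its covered length went from 600 ± 849 bp in WT to 5411 ± 0 bp (AT1G23380, chromosome 1, peak at 8294401 to 8305000 in hda9-1 replicate 2, TAIR10). The hda9-1 peak of KNAT6 also overlapped a WT peak, and its H3K14ac peaks covered 560 bp in WT and 0 in both mutants. ACA1 (AT3G52720), an alpha carbonic anhydrase, had no peak in either WT library and 3543 ± 202 bp in hda9-1 (chromosome 3, 19538601 to 19550400).

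XTH30, a xyloglucan-modifying enzyme, also gained H3K9ac and went from 0 to 2711 ± 0 bp (chromosome 1, 11574001 to 11578600), and TBL41 from 0 to 2360 ± 0 bp. The terpene synthase TPS02 reached 2736 ± 0 bp, the ascorbate peroxidase APX6 2640 ± 56.6 bp, PFA-DSP2 2497 ± 986 bp, UMAMIT30 2493 ± 0 bp, MDP40 2393 ± 0 bp and SHI 2209 ± 0 bp, each from 0 in WT. Among the 1449 gained genes, 818 (56.5%, 95% Wilson interval 53.9% to 59.0%) had a hda9-1 peak that also overlapped a WT peak elsewhere, and 631 (43.5%, 41.0% to 46.1%) had a peak that touched none.

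Genes that lost H3K9ac in hda9-1 included TT10, a laccase-like gene of the seed coat, which went from 2272 ± 181 bp in WT to 0 (chromosome 5, peak of WT replicate 2 at 19490201 to 19492600). The zinc-transporting ATPase HMA4 went from 3106 ± 1264 bp to 0, the anther receptor kinase EMS1 from 2500 ± 1556 bp to 0, the carboxypeptidase-like scpl47 from 2352 ± 141 bp to 0, and AGL79 from 2331.5 ± 2780 bp to 0. The WT spread of AGL79 was larger than its change.

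Lists of genes fixed beforehand were compared by the share gained among members unmarked in both WT libraries. Of 12 such flowering-time genes, CO gained H3K9ac in hda9-1, from 239 ± 0 to 739 ± 424 bp. Of 14 heat and warm-temperature genes, 3 (21.4%, against 7.44% of other genes) gained it: PIF4 (2000 ± 0 to 2900 ± 0 bp), GolS1 (0 to 803 ± 0 bp) and the auxin-synthesis gene YUC8 (400 ± 566 to 1402 ± 424 bp), with Fisher's exact p = 0.0808, adjusted p = 0.485. The call of PIF4 reflects wider peaks, and reads per covered bp of its region were lower than in WT (log2 change -0.81, edgeR, adjusted p over the list 0.000451). Of 3 genes of the acetylation machinery, 2 (66.7%) gained H3K9ac, HAF01 and HD1, the gene of HDA19 (Fisher's exact p = 0.0158, adjusted p = 0.19). SEP3 (0 to 1923 ± 0 bp) and MIR172e (0 to 125 ± 0 bp) gained it among 11 MIR172 and floral genes, and DREB2A (0 to 596 ± 0 bp) and KIN2 (0 to 884 ± 199 bp) among 15 abscisic acid, drought and cold genes. Of 2 senescence genes WRKY53 gained it (0 to 700 ± 141 bp), and SAG13, marked in WT, lost it. RD22 (2156 ± 707 bp to 0) and the clock gene PRR5 (797 ± 283 to 98.5 ± 139 bp) also lost it.

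No gene of the seed maturation, immunity, photosynthesis, housekeeping or pollen lists gained H3K9ac in hda9-1, but no photosynthesis or housekeeping gene could have gained it, since each was marked in at least 1 WT library, and only 1 clock gene could. None of the 12 lists passed adjustment. Among 20 gene families, of which the family of immune receptors matched no gene, pentatricopeptide repeat proteins gained it most often in hda9-1, with 6 of 16 unmarked members (37.5%) against 7.42% of other genes (Fisher's exact test, two-sided, odds ratio 7.49, adjusted p = 0.0141), a call that was lost under 5 other definitions or backgrounds. Of these members 31.2% touched a WT peak, against 8.68% of other protein-coding genes, of which 10.2% gained H3K9ac. Protein-coding genes at the same distance from a WT peak would give 2.56 gains (exact stratified p = 0.0245, a test chosen after the result was seen).

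The difference of 2533 marked genes between hda9-1 and WT was larger than the spread between replicates, and its exact permutation p (two-sided) was 0.333, the smallest that 2 against 2 libraries allow. The covered length differed by 6.14 Mb with the same exact p of 0.333. A simulation in which each gene kept its number of marked libraries and the libraries differed only in their overall yield gave 933 gained genes (range 835 to 1003) and 69.7 lost (46 to 104), both below the observed counts. The number gained was 2539 without WT replicate 1, 3215 without WT replicate 2 and 2319 without hda9-1 replicate 1, and the number lost was 1004, 745 and 336 without WT replicate 1, WT replicate 2 and hda9-1 replicate 2.

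**Figure D2:**
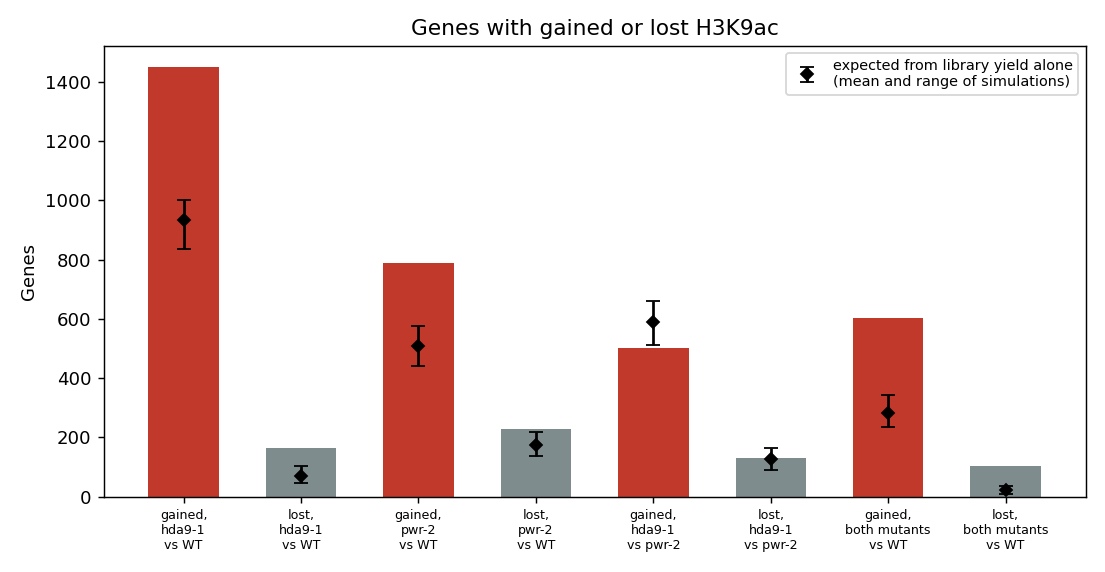
Number of genes that gained or lost H3K9ac in each comparison (bars), with the mean and range of 1000 simulations in which only the yield of the libraries differed. Gains in hda9-1 (1449) and pwr-2 (789) lay above the simulated ranges, and the 503 genes marked in hda9-1 but not pwr-2 lay below theirs.

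The same question was asked of PWR. In pwr-2, 16967.5 ± 1026 genes had a marked end, and 789 genes gained H3K9ac while 227 lost it. ACA1 gained it here too, from 0 to 3443 ± 344 bp. The auxin influx carrier LAX3 went from 0 to 2401 ± 850 bp. FBP, a fructose-1,6-bisphosphatase gene, rose from 900 ± 424 to 3203 ± 0 bp, and CYP707A3, which encodes an abscisic acid hydroxylase, from 0 to 1934.5 ± 756 bp.

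Among genes with a symbol, the 10 largest gains of pwr-2 also included UMAMIT30 (2493 ± 0 bp), LTL1 (2481 ± 566 bp), FMO GS-OX2 (2411.5 ± 165 bp), MSRB6 (1992.5 ± 319 bp) and UMAMIT22 (1818 ± 990 bp). Each of these went from 0 in WT. EMS1, TT10 and the cytochrome P450 gene CYP71A28 (2203.5 ± 179 bp in WT) had no H3K9ac peak in either pwr-2 library. The terpene synthase TPS04 went from 2536 ± 424 bp to 0, and NVL from 2725 ± 1553 to 400 ± 566 bp. Of the 789 gained genes, 466 (59.1%, 95% Wilson interval 55.6% to 62.4%) had a pwr-2 peak that overlapped a WT peak elsewhere.

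Warm-temperature genes were again among the list members that changed in pwr-2. PIF4 (2600 ± 424 bp, against 2000 ± 0 bp in WT), GolS1 (903 ± 141 bp, against 0) and IAA29 (1086 ± 542 bp, against 0) gained H3K9ac, 3 of 14 (21.4%, against 4.04% of other genes), and HSP18.2 lost it (Fisher's exact p for gains 0.0173, adjusted p = 0.207). As in hda9-1, the region of PIF4 held fewer reads per covered bp than in WT (log2 change -0.79, edgeR, adjusted p over the list 0.000603). CO (739 ± 141 bp, against 239 ± 0 bp) and AGL24 (1653 ± 923 bp, against 0) gained H3K9ac among flowering-time genes (Fisher's exact p = 0.0828, adjusted p = 0.467), and HAF01 among genes of the acetylation machinery. SAG13, RD22 and CAB1 lost it. No member of the MIR172, seed maturation, immunity, housekeeping, pollen or clock lists gained or lost it in pwr-2, where as in hda9-1 no housekeeping gene and only 1 clock gene could have gained it. No list passed adjustment, and SAUR genes were the leading family, with 5 of 33 gained, SAUR22, SAUR24 and SAUR26 among them (15.2%, Fisher's exact p = 0.01, adjusted p = 0.2).

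The difference of 1050.5 marked genes between pwr-2 and WT was close to the SD of the pwr-2 libraries (1026), with an exact permutation p of 0.667. It was 540.5 without WT replicate 1, 1776 without pwr-2 replicate 1 and 325 without pwr-2 replicate 2. The covered length differed by 2.82 Mb, with an exact p of 0.333. Simulated differences in yield alone gave 509 gained genes (range 441 to 576) and 176 lost (139 to 217). Gains numbered 1633, 2000, 1646 and 1486 without WT replicate 1, WT replicate 2, pwr-2 replicate 1 and pwr-2 replicate 2, and losses 1220, 912, 341 and 1067. The split of the 4 WT and pwr-2 libraries that put WT replicate 2 with pwr-2 replicate 2 gave 647 genes.

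**Figure D3:**
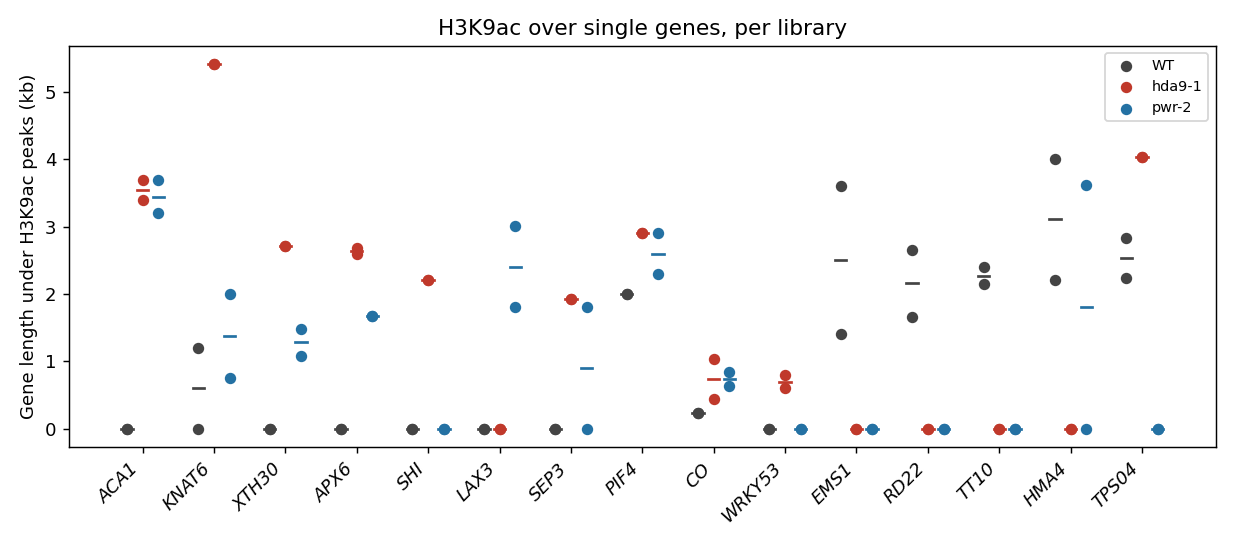
Length covered by H3K9ac peaks (kb) over 15 named genes in each of the 6 H3K9ac libraries; each point is 1 library and each short line the mean of a genotype. ACA1 was uncovered in WT and covered in all 4 mutant libraries, SHI was covered only in hda9-1, LAX3 only in pwr-2, and TT10 and EMS1 only in WT.

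Most genes named beforehand from the literature on HDA9 and PWR were neither gained nor lost. AGL19, MIR172c and MIR172d had no peak in any H3K9ac library, and MIR172a and MIR172b were covered over their full 102 and 95 bp in all 6. FT had a peak in 1 hda9-1 library (2627 bp) and 1 pwr-2 library (1628 bp) and in neither WT library. WRKY57 was covered over 991.5 ± 554 bp in WT, 3346 ± 1079 bp in hda9-1 and 2283 ± 424 bp in pwr-2, and counted as unchanged because WT replicate 1 was marked, while WT replicate 2 was not and all 4 mutant libraries were. APG9 was covered over 300 ± 424 bp in WT and 600 ± 0 bp in each mutant, and NPX1 over 723 ± 1023 bp in WT, 1746 ± 141 bp in hda9-1 and 1146 ± 990 bp in pwr-2, so that the WT replicates of both genes differed as much as the genotypes.

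HDA9 and PWR interact, so the next question was whether the mutants changed the same genes. A total of 604 genes gained H3K9ac in both, which is 76.6% of the pwr-2 gains and 41.7% of the hda9-1 gains, and 104 genes lost it in both. UMAMIT30, ACA1, XTH30, APX6, PIF4, GolS1, CO and HAF01 were among the shared gains, and EMS1, TT10, CYP71A28, RD22 and SAG13 among the shared losses. Independent lists would share 58.7 of 19462 testable genes (odds ratio 68.9), and independent losses 2.81 of 13409 (odds ratio 179, Fisher's exact p = 7.01e-151). Differences in library yield alone gave 283 shared gains (range 234 to 344) and 21.1 shared losses (9 to 37).

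With gains taken from 1 library of each mutant, the odds ratio of the gains was 49.0 for hda9-1 replicate 1 with pwr-2 replicate 2. For hda9-1 replicate 2 with pwr-2 replicate 1 it was 19.2. The testable genes were unmarked in both WT libraries, so this did not remove the shared WT calls. No value for yield alone was computed for these odds ratios. Both WT libraries were shallower than every mutant library, so depth alone could also raise them. Of the 15 ways to set 4 of the 6 libraries against the other 2, the real one gave the most genes, 604, and the next 477, from the split that set WT replicate 1 and pwr-2 replicate 1, both shallow for their genotype, against the rest. The real split itself set the 2 shallowest libraries, those of WT (1.95 and 2.22 M reads), against the deeper ones. Its rank therefore cannot tell genotype from depth. The shared gains numbered 1378 without WT replicate 1, 1734 without WT replicate 2 and 1031 without pwr-2 replicate 1. The shared losses numbered 803 and 551 without WT replicate 1 and 2.

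Read numbers were compared in 8332 regions that held a peak in every H3K9ac library. Reads were counted only inside each library's own peaks, which covered 60.6% and 61.1% of the regions in WT, 73.7% and 77.5% in hda9-1, and 66.7% and 68.9% in pwr-2, so a rise can hold wider peaks as well as more reads. Among genes with a peak in every H3K9ac library, the region of FBP rose by 1.57 in hda9-1 and 1.67 in pwr-2 on the log2 scale and that of WRKY57 by 1.51 and 1.198, while that of HDA9 changed by 0.01 and 0.18. No region passed an adjusted p of 0.05 in edgeR's quasi-likelihood test in any of the 3 comparisons, and the smallest adjusted p was 0.216 for hda9-1 and 0.182 for pwr-2. At an unadjusted p below 0.05 there were 1016 regions for hda9-1 and 1224 for pwr-2, against 416.6 by chance. DESeq2 called 109 regions higher and 45 lower in hda9-1, and 125 higher and 79 lower in pwr-2. In simulated hda9-1 data edgeR found 26% of regions changed 2-fold and 100% of those changed 4-fold.

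Adjusted over the list alone, edgeR's test on regions that overlap list genes called 2 regions in hda9-1 and 5 in pwr-2 over the 12 lists, against 0 over all regions. Of these regions, those of CO, GolS1, TOC1 and PRR5 lay mostly over a neighbouring gene. The region of CO held more reads in both mutants, by 0.96 in hda9-1 (adjusted p over the list 0.0104) and 1.08 in pwr-2 (0.00543), but peaks covered 3400 and 3000 bp of it in WT and 8600 to 9200 bp in the mutants. Per covered bp it changed by -0.27 and -0.32 (edgeR, adjusted p over the list 0.133 and 0.106). The region of RAP2.7, also named TOE1, held more reads by 0.77 in hda9-1 (adjusted p over the list 0.0267) and changed by -0.01 in pwr-2, yet per covered bp it fell by 0.66 in hda9-1 (0.0175). The region of GolS1 rose by 1.00 in pwr-2 (adjusted p over the list 0.0318) and changed by -0.32 per covered bp (0.400). Among clock genes in pwr-2, the region of TOC1 fell by 0.97, that of PRR5 fell by 0.71 and that of LNK1 (AT5G64170) rose by 0.73, each with an adjusted p over the list of 0.0253 in edgeR's test. Per covered bp these changed by 0.23, -0.02 and 0.34 (edgeR, adjusted p over the list 0.6002, 0.986 and 0.227). In hda9-1 the reads of the same clock regions changed by -0.85, -0.59 and 0.48. Of the regions called on reads, only that of RAP2.7 passed per covered bp, with the opposite sign, so the width of the peaks may lie behind these calls. Per covered bp, 6 regions were called in hda9-1 and 4 in pwr-2. That of AT1G07940 rose in pwr-2 (0.66) and all others fell. The region of PIF4 fell by 0.81 in hda9-1 (edgeR, adjusted p over the list 0.000451) and 0.79 in pwr-2 (0.000603), while its reads changed by 0.33 and 0.48. Peaks covered 2000 bp of it in both WT libraries and 5000 to 5400 bp in the mutants.

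Across the 8332 regions the changes of the mutants had a Pearson correlation of 0.744 and a Spearman correlation of 0.732, where regions are not independent replicates. Simulated unchanged groups, both set against the same simulated WT libraries, gave a Pearson correlation of 0.532 (range 0.515 to 0.554). The covariance was 0.105, against 0.0437 (0.0418 to 0.0466) in the simulation, and it was 0.0462 when each mutant had its own WT library. The changes had the same sign in 77.3% of regions, against 68.1% in the simulation.

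**Figure D4:**
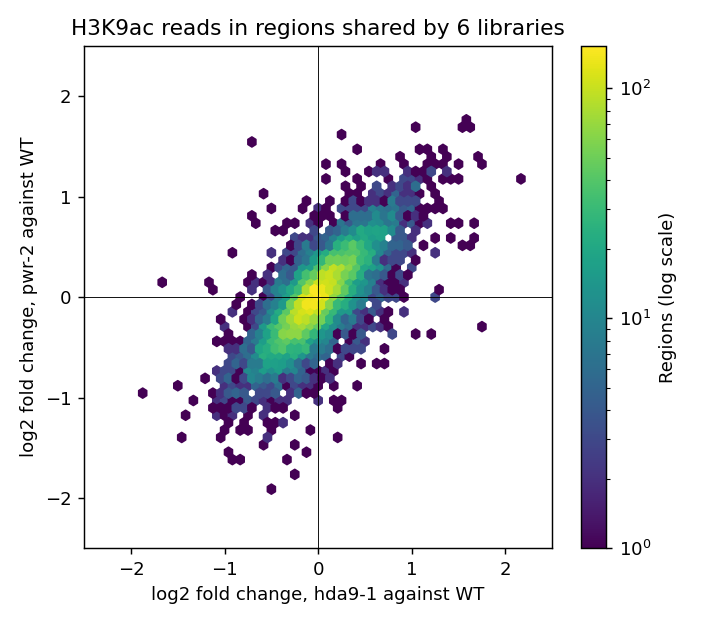
Change in reads from WT (log2) in hda9-1 on the horizontal axis and pwr-2 on the vertical axis for 8332 regions with a peak in all 6 H3K9ac libraries; shading gives the number of regions per cell. The cloud runs along the diagonal, with a correlation of 0.744 against 0.532 in simulated unchanged groups that share simulated WT libraries.

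Set against each other, the mutants differed at fewer genes. A total of 503 genes were marked in both hda9-1 libraries and in neither pwr-2 library, and 129 showed the reverse. SHI belonged to the first kind (2209 ± 0 bp in hda9-1, 0 in pwr-2), as did DREB2A and WRKY53, and LAX3 and MSRB6 belonged to the second. Yield alone gave 588 (513 to 660) and 126 (89 to 163), so the first count lay below its range and the second within it. The 503 became 1356, 859, 844 and 2318, and the 129 became 234, 309, 485 and 636, without hda9-1 replicate 1, hda9-1 replicate 2, pwr-2 replicate 1 and pwr-2 replicate 2. In the read test edgeR called 0 regions (324 at an unadjusted p below 0.05) and DESeq2 called 22 higher and 6 lower in hda9-1.

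H3K14ac was compared to ask whether a second lysine of H3 changed in the same genotypes. A marked end was found in 12226 genes in WT, 14365 in hda9-1 and 14782 in pwr-2. In hda9-1, 3903 genes were marked that were unmarked in WT and 1764 showed the reverse, and in pwr-2 the numbers were 4134 and 1578. The mutants shared 2642 of these gains and 1023 of these losses, measured against the same WT library. The immune receptor kinase gene FRK1 and the indole glucosinolate gene CYP79B2 were marked in both mutants and not in WT, as were the histone deacetylase genes HDT4 and HD2C and the drought genes RD26 and DREB2A. UBQ10, PAD4, ELF3, PSBO2 and LHCB5 were marked in WT and in neither mutant.

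Genes that gained H3K9ac were also more often gained for H3K14ac. In hda9-1, 296 genes gained both marks, against 60.4 for independent lists (odds ratio 8.63, Fisher's exact p = 7.7e-132) and 143 (range 108 to 184) from yield alone. In pwr-2, 140 genes gained both, against 37.3 (odds ratio 5.16, Fisher's exact p = 9.18e-45) and 87.7 (61 to 119) from yield alone. Losses overlapped too: 22 of 41 testable genes that lost H3K9ac in hda9-1 and 35 of 66 in pwr-2 also lost H3K14ac, against 3.43 and 4.61 (Fisher's exact p = 7.83e-14 and 1.13e-23) and, from yield alone, 4.44 (0 to 13) and 10.6 (2 to 21). Part of each overlap is therefore what libraries of unequal yield give. A total of 90 genes were marked in all 6 mutant libraries of both marks and in none of the 3 WT libraries, and 11 showed the reverse.

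Those 90 genes included 33 with a gene symbol. APX6 was covered by H3K9ac over 2640 ± 56.6 bp in hda9-1 and 1680 ± 0 bp in pwr-2, and by H3K14ac over 2400 and 480 bp. NRPE7, which encodes a subunit of RNA polymerase V, was covered over 1554 ± 0 bp in both mutants and AIF1 over 1165 ± 0 bp in both, each from 0 in WT. WRKY60 went from 113 ± 141 bp in WT to 1682.5 ± 98.3 and 1376 ± 532 bp in hda9-1 and pwr-2. MPB2C, BB, GRXC2, UBC30, RAN2 and the immune regulator CBP60G completed the 10 largest. Unmarked here means that peaks covered less than 50% of each end of the gene, and over BB H3K14ac peaks covered 1800 bp in WT, 1000 bp in hda9-1 and 2346 bp in pwr-2. The reverse pattern held for NAP12, TIP5;1, CAD6, FRO5 and HB27, the 5 of the 11 genes with a symbol. EMS1 lost H3K9ac in both mutants while its H3K14ac peaks covered 2800 bp in WT, 3200 bp in hda9-1 and 3000 bp in pwr-2.

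**Figure D5:**
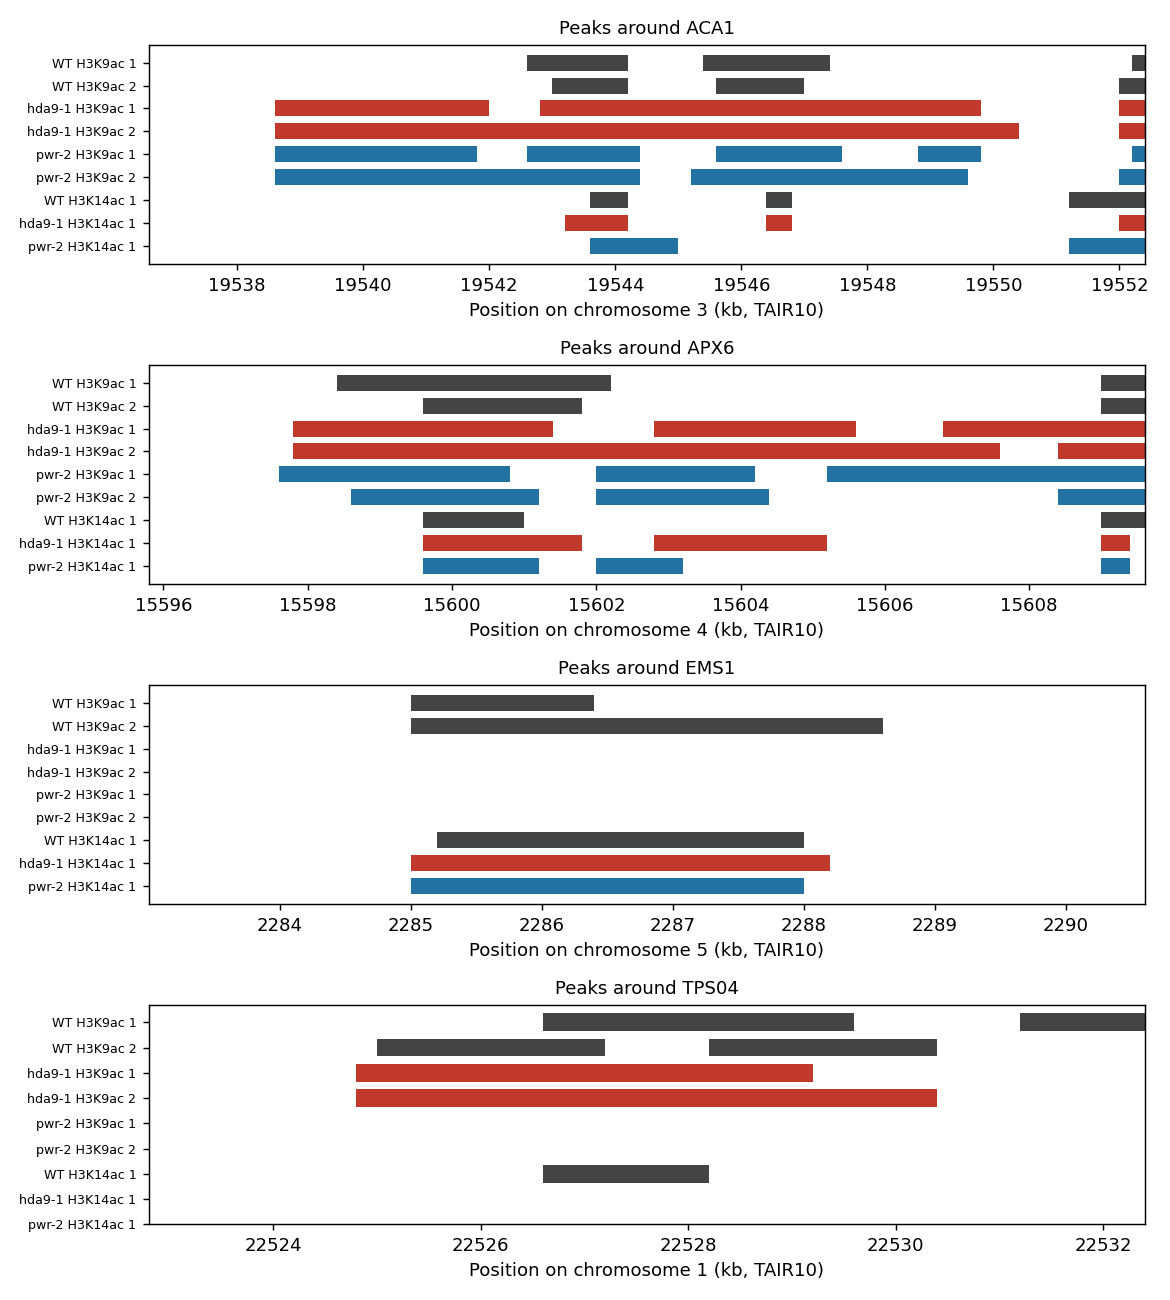
Peaks of the 9 libraries around ACA1, APX6, EMS1 and TPS04 (TAIR10 position on the horizontal axis, 1 track per library, each bar 1 peak). No WT library had a peak over ACA1 or APX6, and EMS1 kept H3K14ac peaks in all 3 genotypes where the mutants had no H3K9ac peak.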

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

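The length of the terpene synthase gene TPS04 covered by H3K9ac peaks moved in opposite directions in the mutants. H3K9ac peaks covered 2536 ± 424 bp of it in WT (mean ± SD, n = 2), 4036 bp in both hda9-1 libraries and 0 in both pwr-2 libraries, so every hda9-1 library lay above WT and every pwr-2 library below it. The difference was not tested. Its strongest peaks held 54.3 and 64.5 reads per kb in WT replicates 1 and 2, against 84.2 and 93.8 over all peaks of those libraries. In hda9-1 they held 277 and 400, against 428 and 597. The signal was thus below the library level in WT and hda9-1 alike, and the wider hda9-1 peaks cannot be told apart from the greater depth of those libraries. The WT peaks that were missing in pwr-2 were weak ones. Its H3K14ac peak covered 1600 bp in WT and was missing in both mutants. It stood out because all libraries of 1 mutant moved one way and all libraries of the other mutant the opposite way. No biological explanation was tested.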

How the results depend on the processing

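The read test and its settings, the covariance, and the rule on 500 bp or 50% of the gene body were chosen after seeing the data. Of the values compared across settings, 353 stayed within 1.5 times or their spread, 66 moved further and 3 reversed. H3K9ac gains outnumbered losses in each mutant under each setting, from 1154 to 1926 gained genes in hda9-1 and 632 to 1170 in pwr-2 with all libraries kept. Of 79 calls on named genes, 40 held under all 8 other settings, and 24 were lost when 90% of an end had to be covered.

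As reported, 1 family passed adjustment, while 0 did with 1 bp of an end, 90% of an end, 1 bp of the body, protein-coding genes only or all genes as background. With gene length as covariate 2 did, pentatricopeptide repeat proteins in hda9-1 and SAUR genes in pwr-2. With 90% of an end, 1 list passed, and genes marked in pwr-2 but not hda9-1 rose to 205. The share of gained genes joined to a WT peak was 47.1% in hda9-1 and 50.7% in pwr-2 with 1 bp of an end, 82.8% and 85.2% with 90%, 45.3% and 49.0% with 1 bp of the body, and 50.4% and 44.8% without the lowest 25% of peaks by count. In hda9-1 it was 63.2% with the same number of peaks in every library and 51.7% for protein-coding genes. Without that 25%, 279 genes were lost in hda9-1, 390 in pwr-2 and 164 in both, and the change of UBC30 in pwr-2 reversed to -57.5 bp, as it did with equal numbers of peaks. Replicates shared 67.3%, 83.0% and 74.5% of peaks (WT, hda9-1, pwr-2) by reciprocal overlap of 50%, against 92.3%, 97.8% and 95.7% by any overlap. The cause was not tested for these. Joining peaks closer than 600 bp moved nothing, since the smallest gap was 800 bp.

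In regions 50% covered by every library (3904), edgeR called 1 region higher and 1 lower in hda9-1, 3 higher in pwr-2 and 0 between the mutants. AT3G29644 rose in both (1.25 and 1.40 on the log2 scale, adjusted p 0.021 and 0.0075), AT-HSFB2B fell by 1.01 in hda9-1, and AT1G69680 and ESE3 rose by 0.59 and 0.70 in pwr-2. RLE size factors, a minimum of 50 reads and each library left out gave 0 calls. With covered length as an offset it called 0 higher and 1 lower in hda9-1, 0 and 2 in pwr-2, and 0 between the mutants. DESeq2 called 109 and 45 for hda9-1, 125 and 79 for pwr-2, and 22 and 6 between them, where edgeR called 0. Differences between replicates 1 and 2 within a genotype, taken over regions, were correlated between genotypes. The correlations were 0.08 (WT with hda9-1), 0.17 (WT with pwr-2) and 0.16 (hda9-1 with pwr-2). The labels tie the replicate numbers to no shared batch, and not every correlation passed 0.1. The replicate numbers were therefore not taken as pairs, and some shared variation is not excluded. A replicate block left edgeR at 0 calls and the gains at 1449 and 789 by construction. Block and 50% coverage together gave 10 higher and 9 lower in hda9-1 and 67 and 82 in pwr-2.

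With 1 of the 6 libraries left out in turn, a call needs 1 library fewer, so counts rise by construction, except where the library belongs to a genotype outside the comparison. Gains ranged from 1449 to 3215 in hda9-1, 789 to 2000 in pwr-2, 648 to 1734 in both and 503 to 2318 for hda9-1 against pwr-2. Losses ranged from 166 to 1004, 227 to 1220, 119 to 803 and 129 to 636. The difference in peak number ranged from -214 (without pwr-2 replicate 1) to 675 for hda9-1 against pwr-2. For pwr-2 against WT it ranged from -204.5 (without WT replicate 1) to 792.5, and was -150.5 without pwr-2 replicate 2. WT depth limits what could be called in WT: a gene without a WT peak is one where none was detected.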

Other observations

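The tests of explanations below were chosen after the results were seen. In the H3K14ac libraries, genes of the circadian clock changed in both directions, a group chosen after its values were seen and not tested. Of 5 clock genes marked in WT, 4 were unmarked in hda9-1, namely PCL1 (also named LUX), PRR7, PRR3 and TOC1, with RVE8 kept, while 14.4% of all genes marked in WT were unmarked there. In pwr-2, 2 of them, PCL1 and TOC1, were unmarked, against 12.9% of all genes. Of the clock genes unmarked in WT, 2 were marked in hda9-1 (ELF4 and RVE1) and 2 in pwr-2 (RVE1 and PRR5), with PRR5 going from 0 in WT to 2146 bp in pwr-2. H3K14ac over TOC1 covered 1200 bp in WT and 0 in both mutants, over PCL1 1000 bp and 0 in both, and over PRR7 1030 bp in WT, 0 in hda9-1 and 720 bp in pwr-2. CO lost H3K14ac in hda9-1, from 2639 bp in WT to 0, while its H3K9ac was gained. GI, which links the clock to flowering, went from 2390 bp in WT to 0 in hda9-1 and 590 bp in pwr-2. With 1 library per genotype and no record of the hour of harvest used here, neither a replicate check nor a time of day can be given.

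The small auxin-responsive SAUR genes did not pass adjustment as a family, with 6 of 33 gained in hda9-1 (Fisher's exact test, adjusted p = 0.288) and 5 of 33 in pwr-2 (adjusted p = 0.2). Among them, SAUR22, SAUR24 and SAUR26 were fully covered by H3K9ac in all 4 mutant libraries (747, 626 and 712 bp). WT replicate 1 had no peak on any of them, and WT replicate 2 covered 87 bp of SAUR22 and none of the others.

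Genes with EMB symbols, named for embryo-defective mutants, gained H3K9ac often in hda9-1: 10 of 21 unmarked ones (47.6%, odds ratio 11.4, Fisher's exact test, adjusted p = 0.000135 over 161 symbol stems), among them EMB1270 and EMB2247, and pwr-2 went the same way with 3 of 21 (14.3%, odds ratio 3.96, Fisher's exact p = 0.0513, adjusted 0.825), a difference between mutants that was not tested. Of other protein-coding genes 10.1% gained H3K9ac in hda9-1. Closeness to WT peaks as the whole cause is argued against. Protein-coding genes at the same distance from a WT peak would give 2.27 gains (exact stratified p = 1.27e-05, not adjusted over the 161 stems). Weak marks that only deep libraries reach may be behind the EMB gains. Of the 10 genes, 9 were also marked in the deeper pwr-2 library and 3 in the shallower one. Other gained protein-coding genes stood at 74.0% and 51.6% there. Depth and genotype cannot be told apart here, as no hda9-1 library had the depth of WT. An effect of HDA9 on these genes stays open, and 5 of the 10 already carried H3K14ac in WT.

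More genes gained than lost H3K9ac in each mutant, and every mutant library had more reads in peaks than any WT library. At equal read density, WT missed genes marked in hda9-1 between 1.14 and 1.40 times as often as the density predicted, and since no hda9-1 library was as shallow as WT, depth and genotype cannot be told apart for these gains. For pwr-2 the ratios ran from 0.953 to 1.13, so greater depth may account for its surplus of gains. Deacetylation by HDA9 with PWR remains an open explanation for both. Losses go against the depth difference, and TT10, EMS1, RD22 and CYP71A28 had no H3K9ac peak in any of the 4 deeper mutant libraries. Their WT peaks were weak, however, at 55.3 to 65.0 reads per kb, against 84.2 and 93.8 over all peaks of WT replicates 1 and 2. In the bins from 50 and 60 reads per kb, WT replicate 1 called 46.4% and 67.2% of genes marked in replicate 2. In reverse it was 37.4% and 58.0%. Losses of such weak peaks therefore do not settle the question of depth.

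Reads in shared regions differed from WT alike in both mutants. The shared WT libraries as the whole cause are argued against by the covariance with separate WT libraries, 0.0462, where simulated unchanged groups reached 0.00306. The deeper against the shallower pwr-2 library went against the hda9-1 change (-0.0164), and the same difference in hda9-1 went against the pwr-2 change (-0.0140). Simulated unchanged groups fell no lower than -0.00361 and -0.00281. This argues against greater depth as the whole cause only over the depths that these libraries span. No mutant library was as shallow as WT, so the step from WT depth stays undecided. The pwr-2 libraries also differed in more than depth, with 69.6% and 78.4% of peak bases in genes. Uneven coverage can account for part of the covariance, which was 0.0182 after the change in covered length was regressed out. It was 0.0261 and 0.0346 in the 3904 and 70 regions that every library covered by 50% and 90%. Simulated unchanged groups reached 0.00293, 0.00292 and 0.0218. Their counts did not depend on covered length. After the regression and at 50% coverage, what uneven coverage alone would leave is therefore not known. In the 70 regions covered by 90%, the covariance above the simulated values argues against uneven coverage as the whole cause there. A joint action of HDA9 and PWR and a difference in preparation between WT and mutant libraries, which no label records, both stay open and were not tested.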
